A study of Homo sapiens with 6 samples.

How the data were processed

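The samples were ChIP libraries of LNCaP cells treated with DMSO or 1 µM BMH-21 for 6 h, made with an antibody against RNA polymerase I or one against RNA polymerase II phosphorylated at serine 5, plus an input library for each treatment. The group of each sample was taken from its title. Each of the 6 groups had 1 sample, and the 2 input libraries were not analysed here.

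The authors' deposited files were 4 lists of peaks, 1 per ChIP library, each with chromosome, start, end, a peak name ending in a running number, and a score per peak. Per the file headers the score column is a p-value, and its values, from 50 upward, are those of a transformed p-value whose exact scale is not stated, so the deposited score is treated as the authors' score and used to rank, filter or describe peaks within a list. The exception is the stricter score threshold, which applies the DMSO median of an antibody to both of its lists although their scales may differ. Per the submitters' processing notes, CASAVA 1.8.2, Bowtie2 2.2.1 and deepTools 3.5.4 were used and the build was hg19. The peak names in the deposited lists begin with MACS, the name of a peak caller, whose version and settings are not given in the sources used here. How inputs entered peak calling, whether duplicate reads were removed and how peaks were selected for the lists are not stated either. The lists have no peak below a score of 50, so a region without a listed peak is not shown to lack the polymerase. Peaks were called per library, as far as the lists show, so library depth and enrichment may set how many peaks pass the caller's threshold, and no adjustment for them was possible.

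Positions were converted from the zero-based starts of the files to the first base as a genome browser shows it. Peak number, covered length, width and score were computed per list. Within a list, the numbers absent between the first number and the highest were counted as skipped, and the share of numbers that is listed was given per list and per chromosome. On a chromosome, skipped numbers were counted between its lowest and highest listed number. Overlap meant 1 bp or more in common. Each share has an exact Clopper-Pearson 95% interval, and a count of 0 is given with the share that 3 counts would make. Random placement moved the peaks of the list being counted to uniform positions on the same chromosome, outside its longest peak-free stretch, while the other list stayed in place. It was run 100 times with fixed seeds unless another number is given, and is a description without a p-value. For the test of skipped numbers, stretches between consecutive listed peaks were compared between lists, and a stretch was nested when it lay wholly inside a stretch of the other list that skipped no number.

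The nested-stretch count was tested on simulated data. From lists of 4000 and 1508 simulated peaks, 600 shared peaks were removed from both, and 962 nested stretches skipped 0 numbers. The 600 numbers then missing from the longer list follow from the removal and test nothing. When 606 peaks of the longer and 620 of the shorter list were removed at random instead, 916 nested stretches skipped 101 numbers.

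Before the data were examined, the comparisons, the alternatives and the rule for named regions were fixed. The rule names, per antibody, the 5 regions with the highest score that are kept, lost or gained, by coordinates where no annotation of the files' build is used, with ties in score ordered by width. As no listed peak was kept, it gave 5 regions from each list, 20 in all. The gene table at hand was on GRCh38, not hg19, so its positions were not used, and planned counts at promoters, in genes, over preset gene lists and on ribosomal DNA were not computed. The planned comparison of kept with lost DMSO peaks had no kept peaks and was not computed. The alternatives fixed beforehand changed the unit counted, the chromosomes, the score threshold, the minimum width and the overlap that counts as shared. The counts of skipped numbers, the clusters, the peaks beside the longest peak-free stretch of a chromosome and their alternatives were chosen after seeing the data. Clusters other than the named ones are described by counts, and those named were chosen after their values were seen. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots matplotlib 3.10.9.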

Results

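Chromatin immunoprecipitation with sequencing was carried out in LNCaP cells, an androgen-responsive human prostate cancer line, after exposure to the solvent DMSO or to 1 µM BMH-21 for 6 h. BMH-21 is a small molecule that intercalates into DNA and inhibits RNA polymerase I (Pol I), the enzyme that transcribes the ribosomal RNA precursor. One antibody was directed against Pol I and the other against RNA polymerase II (Pol II) phosphorylated at serine 5 of its C-terminal repeats. The samples ask where on the genome Pol I and this form of Pol II were found with and without the inhibitor. Pol II peaks below are those of the phosphorylated form. A change in phosphorylation could not be told from a change in the position of Pol II. The series has 6 samples, of which 4 were ChIP libraries with a peak list and 2 were input libraries that were not analysed here. Each antibody and treatment had 1 library. No difference between treatments therefore has a replicate error or a p-value, and the intervals given below are exact Clopper-Pearson 95% intervals that cover counting error over peaks only. Read depth is unknown, because the lists give peaks and no read counts. Positions are on hg19, and no gene annotation of that build was used, so regions are named by coordinates.

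For Pol I, the list after BMH-21 was far shorter than the list from DMSO. The DMSO list held 42547 peaks covering 21.6 Mb, and the BMH-21 list held 1932 peaks covering 0.694 Mb, a ratio of 22.02 in number and 31.1 in covered length. The ratio in number was 65.3 among peaks with a score at or above the DMSO median and 91.5 among peaks of at least 300 bp, and the ratio in length was 48.9 at that score. The score ratios apply the DMSO threshold to both lists, whose scales may differ. These counts need a second figure beside them, since each peak carries a running number and the lists skip many of these numbers. The highest number was 55470 in the DMSO Pol I list, of which 12923 numbers (23.3%) were skipped, and 15755 in the BMH-21 Pol I list, of which 13823 (87.7%) were skipped. By highest number, which is a lower bound on the peaks first numbered, BMH-21 stood at 0.284 of DMSO, a 3.52-fold difference in place of the 22.02-fold difference between the lists. The ratios by score and by width have no such counterpart, since scores and widths of skipped peaks are not given.

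The Pol I regions with the highest score in the DMSO list were on chromosome 16 at 4321173 to 4323750 (score 1326.79) and at 85644522 to 85647070 (1109.71), on chromosome 1 at 28836116 to 28838391 (1105.75), on chromosome 22 at 50967999 to 50970828 (score 1036) and on chromosome 21 at 45079033 to 45080240 (1031.38). None of these was overlapped by a listed peak of another library. In the BMH-21 list the leading Pol I region was on chromosome 5 at 82832792 to 82837096, with a score of 3100. It was followed by chromosome 8 at 43833230 to 43838882 (1953.14), chromosome 2 at 217538747 to 217540655 (1745.42), chromosome 12 at 125396140 to 125398404 (score 1671.3) and chromosome 11 at 2152253 to 2154478 (1553.34). The regions on chromosomes 5, 2 and 11 were also overlapped by BMH-21 Pol II peaks, and the region on chromosome 8 bordered the longest peak-free stretch of that chromosome. All 4 lists covered the 22 autosomes, X and Y, with 0 peaks on unplaced sequence. The 45S ribosomal DNA repeats, which Pol I transcribes, lie on chromosome arms that hg19 largely leaves out, so their occupancy was not measured here.

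For Pol II, the DMSO list held 28798 peaks covering 16.8 Mb and the BMH-21 list 11540 peaks covering 4.97 Mb, a ratio of 2.50 in number and 3.38 in covered length. Among listed peaks only, the ratio in number was 5.83 at or above the DMSO median score and 6.20 for peaks of at least 300 bp. By highest number the libraries were close, with 55439 for DMSO and 50244 for BMH-21, a BMH-21 to DMSO ratio of 0.906. The DMSO Pol II list skipped 26641 of its numbers (48.1%) and the BMH-21 Pol II list 38704 (77.0%). With 1 library each, whether either ratio exceeds the spread between replicates was not measurable.

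**Figure D1:**
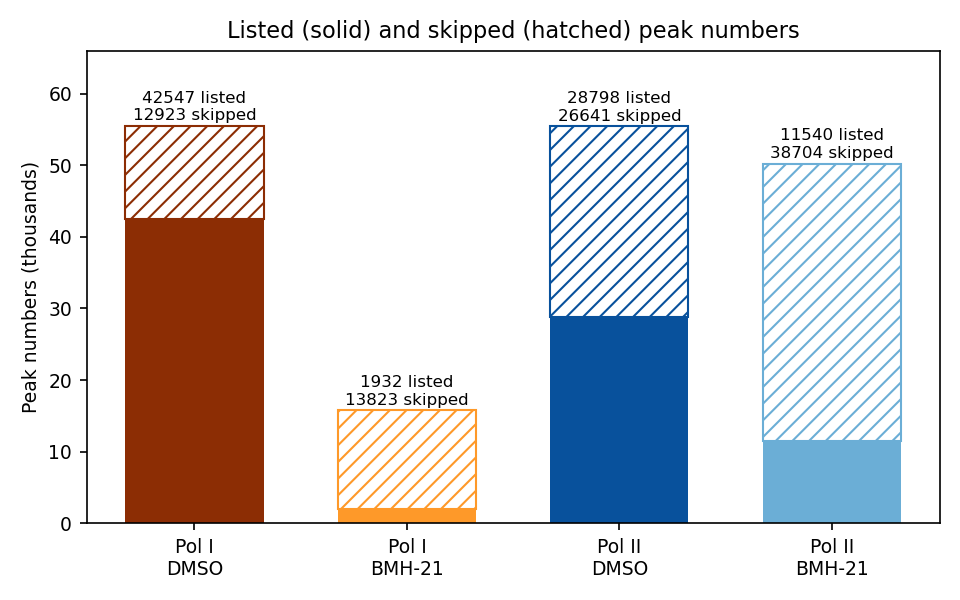
Listed (solid) and skipped (hatched) peak numbers, in units of 1000, for the 4 ChIP libraries, 1 library per bar. The bars reach the highest number of each list, which is 15755 for Pol I after BMH-21 and between 50244 and 55470 for the other libraries.

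The highest-scored Pol II regions of the DMSO list were on chromosome 14 at 24573509 to 24577643 (1651.99), chromosome 12 at 57632585 to 57635230 (1455.38), chromosome 19 at 23510022 to 23514845 (score 1231.6), chromosome 5 at 172749665 to 172753091 (1189.38) and chromosome 1 at 43831753 to 43834292 (1188.58). The last of these was also overlapped by a DMSO Pol I peak. In the BMH-21 list, the Pol II region on chromosome X at 44818177 to 44825485 had the highest score, 3120.65. Chromosome 4 at 102045880 to 102063172, chromosome 1 at 84626143 to 84641750, chromosome 14 at 30354993 to 30370529 and chromosome 5 at 54711805 to 54725702 each had a score of 3100, and were named among the peaks tied at it because they were the widest. That value, or a higher one, was held by 15 BMH-21 Pol II peaks.

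Most peaks listed after BMH-21 were narrow and weakly scored for both antibodies. The median width was 216 bp in the BMH-21 Pol I list against 464 bp in the DMSO Pol I list, and 269 bp against 498 bp for Pol II. Scores below 100 made up 83.6% of the BMH-21 Pol I list and 86.5% of the BMH-21 Pol II list, against 51.1% and 64.7% of the DMSO lists. The score is the authors' own value per peak, and its scale may differ between libraries, so these shares describe each list and do not measure a change at any region. Of the BMH-21 numbers, 87.7% (Pol I) and 77.0% (Pol II) were skipped, against 23.3% and 48.1% of the DMSO numbers. Widths and scores of skipped peaks are not given, so the peaks first called may differ from those listed. At the other end, 18 BMH-21 Pol II peaks were wider than 10 kb, against 0 in either DMSO list. The widest ran over 133 kb of chromosome 21, from 17783740 to 17916828, with a score of 164.12.

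**Figure D2:**
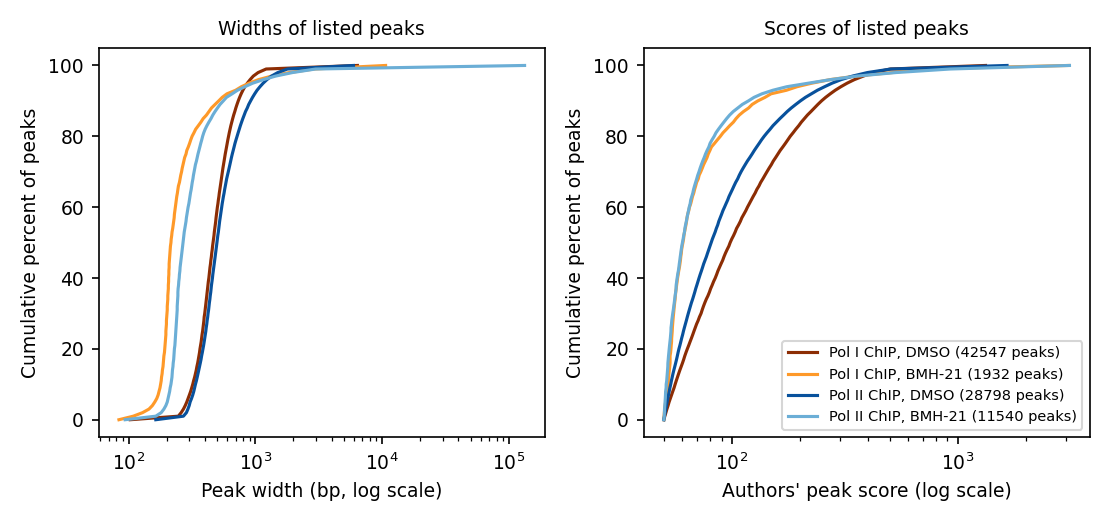
Percentiles of peak width in bp (left) and of the authors' peak score (right) in the 4 lists, both on log axes, with the cumulative percent of peaks on the vertical axis. The BMH-21 curves lie to the left of the DMSO curves over most of their range, with medians of 216 and 269 bp against 464 and 498 bp, and cross them at the top.

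The DMSO and BMH-21 lists of an antibody shared no position. Of 42547 DMSO Pol I peaks, 0 were overlapped by a BMH-21 Pol I peak by 1 bp or more, while randomly placed peaks gave a mean of 22.8. A count of 3 would make 0.00705% of the listed peaks. That share is no limit on the peaks kept, since 12923 DMSO Pol I numbers were skipped. Of 28798 DMSO Pol II peaks, 0 were overlapped by a BMH-21 Pol II peak, against 121 by random placement. In the other direction the counts were also 0, of 1932 BMH-21 Pol I peaks and of 11540 BMH-21 Pol II peaks, against 24.5 and 123 by random placement. Close neighbours were frequent all the same. Within 1 kb of a DMSO Pol II peak lay 2216 BMH-21 Pol II peaks (19.2%, interval 18.5 to 19.9), against 325 by random placement, and within 1 kb of a DMSO Pol I peak lay 243 BMH-21 Pol I peaks (12.6%, interval 11.1 to 14.1), against 78.6.

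The skipped numbers followed the other treatment's list. Where the stretch between consecutive listed peaks of one list fell wholly inside such a stretch of the other list of the same antibody that skipped no number, the inner stretch skipped 0 numbers in all of 2704 cases, whereas the average density of skipped numbers gave 683. For lists of different antibodies the count was above 0 and went both ways against density. With a Pol I list inside, 416 numbers were skipped in 4892 such stretches, against 1140 by density, and with a Pol II list inside, 4119 in 11801 stretches, against 1254. The number of peaks kept by a treatment could therefore not be read from the overlap of these lists.

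Listed Pol I and Pol II peaks of the same treatment overlapped far more often than by random placement. In the DMSO libraries, 5948 Pol I peaks (13.98%, interval 13.7 to 14.3) were overlapped by a Pol II peak, 12.4 times the random mean of 479. In reverse, 5902 DMSO Pol II peaks (20.5%, interval 20.03 to 20.97) were overlapped by a Pol I peak. In the BMH-21 libraries, 184 Pol I peaks (9.52%, interval 8.25 to 10.9) were overlapped by a Pol II peak, 29.5 times the random mean of 6.23, and 186 Pol II peaks (1.61%, interval 1.39 to 1.86) by a Pol I peak. Across treatments, 1036 DMSO Pol I peaks (2.43%) were overlapped by a BMH-21 Pol II peak, 6.52 times the random mean, and 70 BMH-21 Pol I peaks (3.62%) by a DMSO Pol II peak, 3.80 times the random mean. Differences between these folds were not tested. The shares describe listed peaks only, since an overlap with a skipped peak could not be counted. Skipped numbers made up 23.3% (DMSO) and 87.7% (BMH-21) for Pol I, and 48.1% and 77.0% for Pol II.

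Higher-scored listed peaks coincided more often with listed peaks of the other antibody. When DMSO Pol I peaks were ordered by score into 5 equal bins, the share overlapped by a Pol II peak went from 9.38% (interval 8.77 to 10.0) in the lowest bin to 19.8% (interval 18.9 to 20.6) in the highest. The share of DMSO Pol II peaks overlapped by a Pol I peak went from 14.2% (interval 13.3 to 15.1) to 30.7% (interval 29.5 to 31.9). Among BMH-21 Pol I peaks it went from 3.88% (interval 2.19 to 6.31) to 21.96% (interval 17.9 to 26.4). The median score of DMSO Pol I peaks under a Pol II peak was 119.62, against 95.56 for the rest, and their median width was 503 bp against 458 bp.

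Along the genome, the listed share of DMSO numbers differed between some chromosomes for both antibodies, with intervals that did not overlap and no test across chromosomes. For Pol I it ran from 74.0% on chromosome 21 (interval 70.7 to 77.0) to 80.0% on chromosome 22 (interval 77.0 to 82.7), with a median of 76.7% over 24 chromosomes, and was 79.1% on chromosome 2 (interval 77.8 to 80.4) against 75.7% on chromosome 1 (interval 74.5 to 76.9). For Pol II it was 59.6% on chromosome 22 (interval 56.5 to 62.6), 58.8% on chromosome 16 (interval 56.9 to 60.7) and 58.1% on chromosome 19 (interval 56.3 to 59.8), against 45.9% on chromosome Y (interval 39.3 to 52.7), 46.7% on chromosome 8 (interval 44.6 to 48.8) and 47.0% on chromosome X (interval 43.99 to 49.99). Chromosome 19 also had the highest density of DMSO peaks, 31.0 Pol II and 21.6 Pol I peaks per Mb, and chromosome X the lowest, 3.38 and 5.48.

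In the BMH-21 lists too, peak density was highest on chromosome 19, at 9.63 Pol II and 1.24 Pol I peaks per Mb, and lowest on chromosome X, at 1.57 and 0.342. The listed share of BMH-21 Pol II numbers was highest on chromosome 18, at 34.4% (interval 31.5 to 37.4), followed by chromosome Y at 31.5% (interval 25.8 to 37.6), chromosome 21 at 31.3% (interval 28.6 to 34.1) and chromosome 5 at 29.3% (interval 27.8 to 30.9), against a median of 22.9%. On chromosome 18, 1 cluster described below held 177 of the 347 listed BMH-21 Pol II peaks. On chromosome 21 the number of BMH-21 Pol II peaks came to 0.918 of the number of DMSO Pol II peaks, against 0.293 on chromosome 20. For Pol I, chromosome Y had the highest BMH-21 to DMSO ratio, 0.192, and chromosome 3 the lowest, 0.0277.

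**Figure D3:**
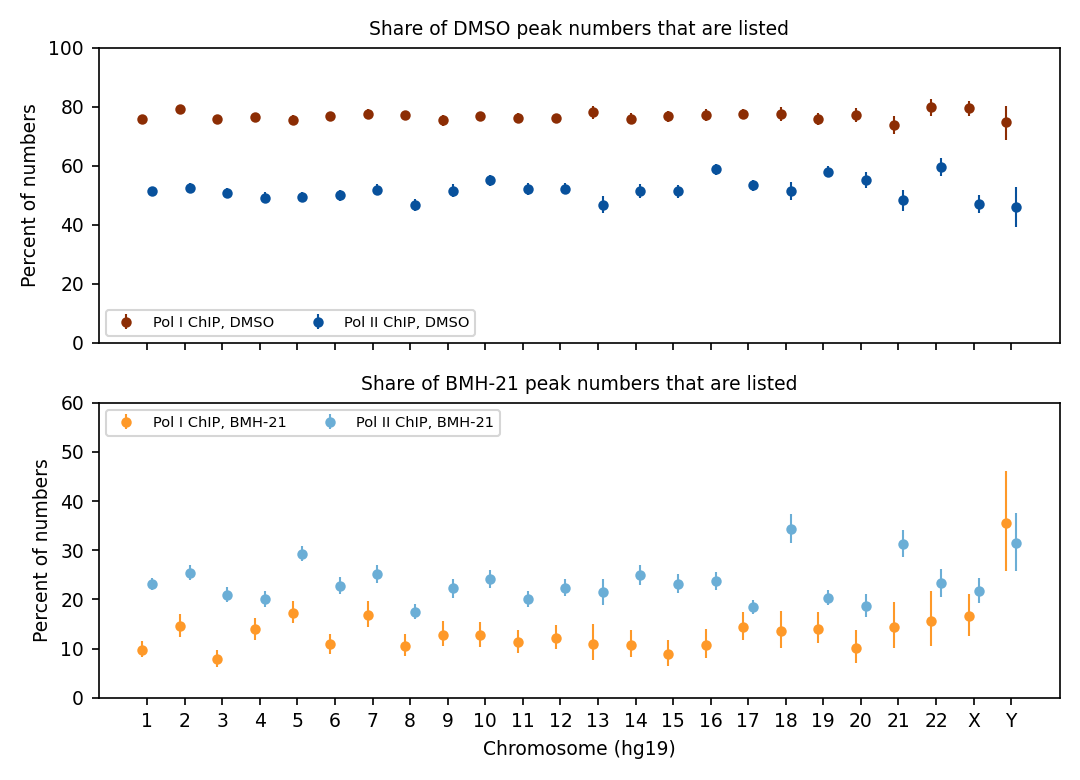
Percent of peak numbers that are listed, per chromosome of hg19, for the DMSO libraries (top) and the BMH-21 libraries (bottom), with 1 library per antibody and bars for exact 95% binomial intervals. The DMSO Pol I points lie between 74.0% and 80.0%, and the BMH-21 Pol II points on chromosomes 5, 18, 21 and Y lie above the median of 22.9%.

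Dense runs of Pol II peaks were found in both treatments. A cluster was taken as 10 or more listed peaks with no gap over 10 kb, a definition chosen after the data were seen, and no cluster appeared in 20 random placements of any list. The DMSO Pol II list had 260 clusters with 5125 peaks (17.8% of the list) over 13.4 Mb, with 25.2% of their length under peaks. The largest by peaks were on chromosome 16 at 89327953 to 89539673 (212 kb long), chromosome 5 at 107196553 to 107459173 (109 peaks) and 106705975 to 106998013 (102 peaks), and chromosome 10 at 25557335 to 25777573 (99 peaks).

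The BMH-21 Pol II list had 54 clusters with 1766 peaks (15.3% of the list) over 3.42 Mb, with 56.3% of their length under peaks. Of these, 5 touched a DMSO Pol II cluster, on chromosomes 2, 8 and Y. In 20 of the 54 the top score was 1000 or more, and these 20 spanned 1.96 Mb on 13 chromosomes with 84.9% of their length under peaks. The largest were on chromosome 18 at 55823391 to 56074257 (177 peaks), chromosome 21 at 22370429 to 22549929 (151 peaks), chromosome 14 at 30133304 to 30246048 (92 peaks), chromosome 5 at 54708698 to 54831090 (86 peaks), chromosome 6 at 76500529 to 76609101 (79 peaks) and chromosome 11 at 113976609 to 114075342 (72 peaks). Within each of these 6 regions the BMH-21 Pol II numbering skipped 0 numbers and the DMSO Pol II list had 0 peaks. Of the 20 clusters, 16 had neither a skipped number nor a listed DMSO Pol II peak. In the other 34 clusters, 26 held a listed DMSO Pol II peak, 171 numbers were skipped and 17.7% of the length was under peaks. As the 2 Pol II lists share no position, a listed DMSO peak could lie only between the BMH-21 peaks of a cluster. The counts of clusters with such a peak therefore depend on the length left free. The cluster on chromosome 4 at 101935944 to 102089715 was 99.4% covered by 18 peaks. Outside clusters, the BMH-21 Pol II peaks had a median width of 257 bp, and the listed share of their numbers ran from 14.1% on chromosome 21 to 27.4% on chromosome Y, so that chromosome 21 changed from among the highest to the lowest when its clusters were left out. Chromosome 18 went from 34.4% to 20.4% and chromosome 5 from 29.3% to 22.3%, against a median of 20.1% outside clusters. Clusters are runs of listed peaks by definition, with 90.7% of their numbers listed, so leaving them out lowers this share largely by construction.

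**Figure D4:**
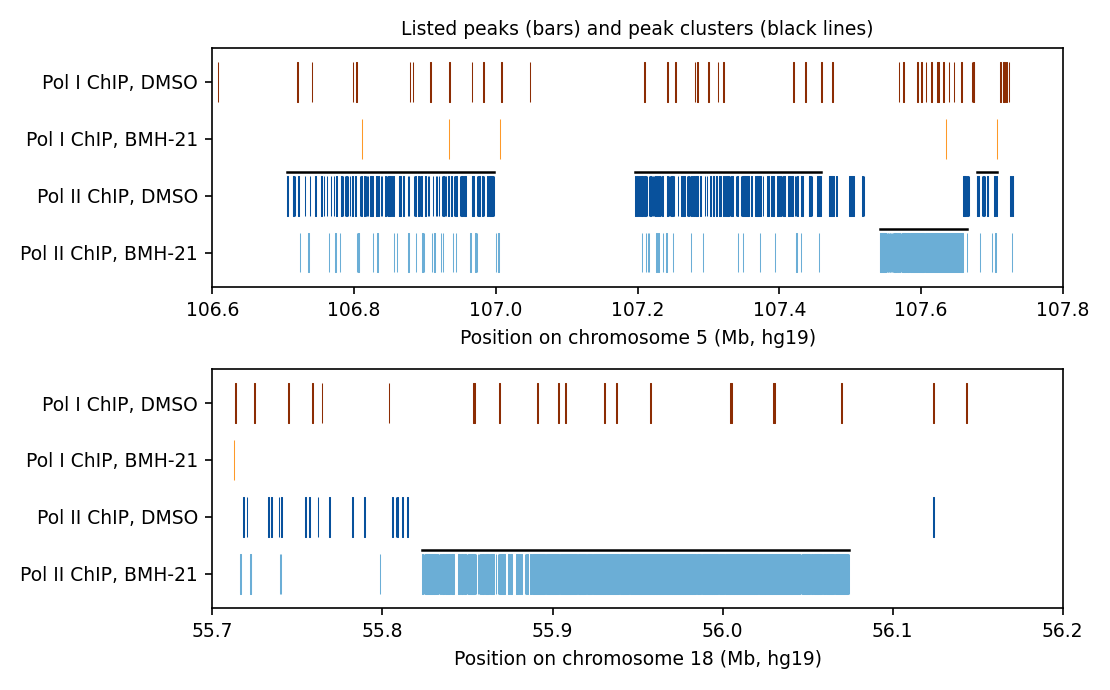
Listed peaks of the 4 libraries (vertical bars, narrow peaks drawn at a minimum width) and clusters (black lines) along chromosome 5 (top) and chromosome 18 (bottom), with position in Mb on hg19. The BMH-21 Pol II clusters at 107541786 to 107664967 on chromosome 5 and at 55823391 to 56074257 on chromosome 18 lie beside stretches with DMSO Pol II peaks, of which the chromosome 18 cluster holds 0 and the chromosome 5 cluster 3.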

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

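The alternatives for skipped numbers, clusters and the peak-free stretch were chosen after the data were seen, and the others before. Of 94 alternative values over 30 results, 58 stayed within 1.5 times the main count, length or ratio or within the interval of the main share, and 36 did not. Keeping only scores at or above the DMSO median of the antibody left 21283 and 326 Pol I peaks (DMSO, BMH-21) over 13.2 and 0.269 Mb, and 14402 and 2471 Pol II peaks over 10.7 and 2.47 Mb. The DMSO peak numbers follow from this threshold by construction, while the BMH-21 numbers depend on the scores of those lists. The DMSO to BMH-21 ratio of peak number became 65.3 for Pol I and 5.83 for Pol II, and that of covered length 48.9 for Pol I. A minimum width of 300 bp left 434 BMH-21 Pol I and 4471 BMH-21 Pol II peaks, with ratios of 91.5 and 6.20. With neighbours within 1000 bp counted as shared, the shares became 0.578% (Pol I) and 8.74% (Pol II) of listed DMSO peaks and 12.6% and 19.2% of listed BMH-21 peaks. They count listed neighbours and do not measure the peaks kept, since skipped peaks could not be counted. Each other setting only narrows an overlap that is already 0, so its share of 0 was fixed beforehand. Those shares are counted among the 58 but do not test robustness. DMSO Pol I peaks overlapping Pol II peaks came to 13.4% with 50% of the shorter peak, 18.1% within 1000 bp and 10.5% at the stricter score, and BMH-21 Pol I peaks to 15.01% and 11.04% under the last 2. Clusters with gaps up to 5000 bp numbered 1 in DMSO Pol I, and with gaps up to 20000 bp 52 in DMSO Pol I and 92 in BMH-21 Pol II. With at least 20 peaks, clusters numbered 0 and 1 for Pol I (DMSO, BMH-21) and 75 and 25 for Pol II. Within 1 Mb of the longest peak-free stretch lay 1.11% and 7.66% of Pol I peaks and 0.938% and 3.10% of Pol II peaks, and without the peaks that bound it the BMH-21 Pol I share was 3.57%. Where the construction does not show it, the cause was not tested. The DMSO list was longer than the BMH-21 list for each antibody under each alternative of peak number. Alternatives for promoters, genes, gene lists and ribosomal DNA were not run, as no hg19 annotation was used. No paired analysis was possible because each group had 1 library. Read depth is unknown, so its effect on peak number could not be measured.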

Other observations

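All the tests of this part were chosen only after the result was seen. The BMH-21 Pol I list held 10 clusters of 10 or more peaks, with 133 peaks (6.88% of that list). The largest, on chromosome 7 at 128477387 to 128499262, had 25 BMH-21 Pol I peaks, 0 skipped numbers and 0 listed peaks of the other libraries. The next, on chromosome 5 at 38475487 to 38504285, had 15 BMH-21 Pol I peaks and 2 BMH-21 Pol II peaks. Others were on chromosome 4 at 190986312 to 191012763 (14 peaks) and chromosome 10 at 135473732 to 135501430 (13 peaks). They held 12 and 10 BMH-21 Pol II peaks, and the last peak of any list on these chromosomes ended at 191042001 and 135523525. The cluster on chromosome X at 61682034 to 61723536 began where the longest peak-free stretch ended. That on chromosome 8 at 46847106 to 46877517 lay within 100 kb of such a stretch. Clusters with a top score of 1000 or more were on chromosome 5, at 71489641 to 71505431 (top score 1089) with 9 BMH-21 Pol II peaks and at 146770377 to 146795453 (top score 1470.68) with 4. The DMSO Pol I list had 11 clusters with 138 peaks (0.324% of that list), the largest on chromosomes 11, 12 and 22 with 16 peaks each.

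The lists of an antibody shared no position, although each skipped many numbers. A candidate explanation is that peaks overlapping the other treatment were removed before deposit, and the 0 skipped numbers in nested stretches are what that needs. A filter unrelated to the other treatment is argued against by the 683 skipped numbers that density gives for the same stretches. Density is a rough guide only, as it missed both ways for lists of different antibodies. There, 416 numbers were skipped against 1140 by density with Pol I inside, and 4119 against 1254 with Pol II inside. A move of every Pol I peak to a place of its own after BMH-21 is argued against by the 87.7% of BMH-21 Pol I numbers that are skipped. Under the removal hypothesis the skipped numbers would be peaks shared by both treatments, and the lists treatment-specific peaks.

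Of the 20 BMH-21 Pol II clusters with a top score of 1000 or more, 16 held no listed DMSO Pol II peak. Such a peak could lie only in the part of a cluster not under BMH-21 Pol II peaks. Extra DNA copies or collapsed sequence in the BMH-21 chromatin would also give peaks in the Pol I library of the same treatment. If skipped DMSO Pol I numbers are peaks shared with BMH-21, at least 21 and at most 45 of the 54 clusters held a BMH-21 Pol I peak (13 to 19 of the 20). By listed peaks alone, 2 of the 20 held a BMH-21 Pol I peak under a cluster peak, and 19 a DMSO Pol I peak. In the other 34 clusters these counts were 7 and 10. The counts are not alike in base: the lists held 42547 DMSO and 1932 BMH-21 Pol I peaks. Under the peaks of all 54 clusters lay 129 of the former and 23 of the latter. Cluster peaks covered 84.9% of the length of the 20 clusters and 17.7% of that of the 34. Extra copies would not lead to Pol I peaks listed in DMSO only. With 1 library per group and part of the peaks only inferred, these counts leave that explanation open. Phosphorylated Pol II may instead have shifted along regions it also left: 16 of the 54 clusters (5 of the 20) lay within 500 kb of a DMSO Pol II cluster. For the 54, at most 12 did so in 1000 random placements, but 270 of 1000 equal draws of BMH-21 Pol II peaks outside clusters on the same chromosomes gave as many. The 20 were not placed or drawn separately. The test therefore leaves a shift open, as it does an effect of BMH-21 and a fault of 1 library or its input.

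Peaks beside the longest peak-free stretch of a chromosome, which on most chromosomes is the gap at the centromere, were frequent in the BMH-21 Pol I list. Within 100 kb of it lay 88 peaks (4.55%), 26.1 times the mean of random placement (20.5 times without the 19 that bound the stretch by construction), with 20.7% of the list's covered length, led by chromosome 8 at 43833230 to 43838882 and chromosome 17 at 22258886 to 22262214 (score 1398.38). Repeats beside these gaps that gain reads in any BMH-21 library are a candidate explanation, since the BMH-21 Pol II list without its 7 bounding peaks also stood at 3.46 times random (65 peaks, at most 36 in a placement). The DMSO lists did not exceed their placements, but this cannot serve as support. Under the removal hypothesis, repeat peaks present in both treatments would be missing from the DMSO lists as well. A constant background share that stands out because few other Pol I peaks are left stays open. The length covered there was 3.81 times that in the DMSO Pol I list, but this ratio cannot test it, since peaks present in both libraries would be missing from both lists under the removal hypothesis. A biological gain of Pol I at these places was not tested.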
